A study of Canis lupus familiaris with 29 samples.

How the data were processed

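FPKM values of 29 MDCKII libraries were analysed, in 13 groups taken from the sample labels. Per the labels, cells were grown in Eagle's medium, seeded on matrigel or on transwell inserts, and RNA was made into stranded mRNA libraries. The authors deposited 1 FPKM file per library, with a value for each of 24223 Ensembl dog genes, and per the submitters' processing notes HISAT2 2.1.0 and Cufflinks 2.2.1 and the dog builds canFam3 and CanFam3.1 were used, with no role given for each. Further scaling between libraries was not given in the sources used here. Read counts were not used here, so absolute depth is unknown. Depth relative to day 0 replicate 2 was read from the steps between FPKM values under 0.15.

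Of the genes, 15796 had a symbol of their own, 5715 had no symbol and 2712 shared one. Of all genes 7703 were at 0 in all libraries. Genes with at least 1 FPKM in at least 2 libraries were tested, 11774 in number, of which 1726 had no symbol of their own and were counted but not named. No coordinates were used, since the gene table at hand is of another build. Of 5370 genes with a mean of at least 10 FPKM, 61 were listed at 0 in some library. No pair of libraries was identical.

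Log2(FPKM + 1) was fitted with limma 3.58.1 (trend) in R 4.3.3, with 1 mean per group over all 29 libraries, and contrasts were tested 2-sided with Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. The 18 contrasts set each 3D and 2D time point against day 0, 3D day 8 against 24 h, 2D day 11 against day 4, the mean of 3D days 3, 5 and 8 against that of 2D days 4 and 11, each knockdown against wild type at day 0 and 2D day 4, the change of that difference between these days (interaction), the knockdowns against each other, and DENND5A-KD 2D day 7 against day 4. The day 14 library was described without a test. Gene lists for mitosis, DNA replication, polarity complexes, tight junctions, adherens junctions and desmosomes, apical membrane, apical trafficking, the DENN family and RAB partners, primary cilium, basement membrane, mesenchymal markers, YAP and TAZ targets, cytoskeleton, glycolysis, oxidative phosphorylation, cholesterol synthesis, distal nephron transport, intercalated cells, interferon-stimulated genes, NF-kB and cytokines, the unfolded protein and integrated stress response, p53 targets, immediate early genes, TGF-beta and BMP, Wnt, ribosomal proteins, heat shock, fibroblasts, endothelium and leukocytes were written before the data were examined. They were tested with camera (correlation between genes of 0.01), and again with a correlation estimated from the data. Genes were named by a rule, the 8 largest fold changes in either direction with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the groups, plus members of lists with the smallest adjusted p, and some genes that met it are not used here. DENND5A and AVL9 were always named.

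Alternatives were quantile normalization, median-ratio scaling, a pseudocount of 0.1, no expression filter, replicate or line number as a block (duplicateCorrelation or a fixed term), fitting the groups of a contrast alone and leaving out each library. A batch term for the 5 wild-type libraries that stand apart, and their omission, were added after seeing the data. The batch term left out day 14. Whether libraries with the same number pair was checked from the correlation of their deviations from group means. Knockdown lines of 1 number pair by design. Shared controls were handled by simulating unchanged groups 100 times and by splitting the day 0 libraries.

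The pipeline was tested on simulated data with changes put into 200 of 11774 genes. At a log2 change of 1 it recovered 76.1 to 91% of changed genes in the wild-type contrasts except 3D against 2D (97%), 70.1 to 91% in the knockdown contrasts and 56.7 and 50.7% in the interactions. At a log2 change of 0.5 it recovered 3 to 74.6%, and at 2, 93.9 to 100%, and 3 to 16 unchanged genes were called per contrast. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures.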

Results

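Gene expression was measured by RNA sequencing in MDCKII cells, a dog kidney epithelial line, in 29 libraries and 13 groups. Wild-type cells were taken at seeding (day 0, n = 4), as 3D cysts on matrigel at 24 h, day 3, day 5 and day 8 (n = 2 each) and day 14 (n = 1). As 2D cultures on transwell inserts they were taken at day 4 and day 11 (n = 3 each). Cells carrying a knockdown (KD) of DENND5A or of AVL9, genes of the DENN domain family, were taken at day 0 and 2D day 4 (n = 2 each). DENND5A-KD cells were also taken at 2D day 7 (n = 2). The knockdown samples carry the numbers 1 and 2 for DENND5A and 1 and 4 for AVL9, here called lines. The labels do not say whether these numbers mark clones, hairpins or guides. No control line treated the same way is among the samples. The labels also do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Fold changes are log2 differences of FPKM + 1 with their standard errors, and understate the change of genes with low FPKM.

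Total FPKM per library ran from 276017 to 441332, and 10163 to 10903 genes reached 1 FPKM. Depth relative to day 0 replicate 2 ran from 0.45 to 1.66. A set of 5 wild-type libraries stood apart: replicate 1 of day 0, 3D day 3, 3D day 8 and 2D day 4, and the day 14 library. The 5 were picked by low relative depth, 0.45 to 0.72 against 0.83 to 1.1 in other wild-type libraries. TIMM13, a chaperone of mitochondrial import, was listed at 0 in all 5 and at 30.9 to 397 FPKM in the other 24 libraries. RPS27L, a ribosomal protein paralog, read 11.6 to 22.3 FPKM in the 5 and 0 to 1.37 in the others. TMSB10, which binds monomeric actin, read 0 to 223 FPKM in the 5 and 1030 to 3540 in the rest. Deviations from group means in the 4 replicated libraries correlated across genes with r of 0.40 to 0.56. In these 4, 604 genes lay more than 0.2 log2 above and 244 more than 0.2 below the other libraries of each group. Each count below is therefore given also with a batch term for these libraries and without them, choices made after seeing the data. Counts without them are left out where 3D day 3 or 8 keeps 1 library. Of 151 list calls with camera, 5 held with an estimated correlation. Each such library was also set against day 0 replicate 1, and the others against the other day 0 libraries. These fold changes correlated across genes with r of 0.81 at 3D day 3, 0.84 at 3D day 8 and 0.89 at 2D day 4.

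**Figure D1:**
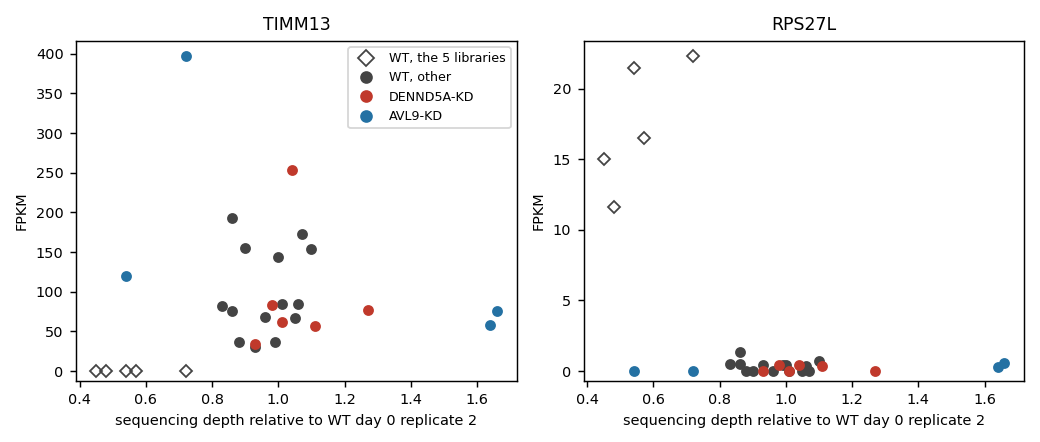
FPKM of TIMM13 (left) and RPS27L (right) on the vertical axes against sequencing depth relative to wild-type day 0 replicate 2, 1 point per library. Open diamonds are the 5 wild-type libraries that stood apart, with TIMM13 listed at 0 and RPS27L at 11.6 to 22.3 FPKM, and filled circles are the other 24 libraries.

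The targeted genes were lower in the lines labelled as their knockdowns. DENND5A (ENSCAFG00000007156) read 5.62 ± 0.895 FPKM (SD, n = 4) in wild-type and 1.95 ± 0.0975 (SD, n = 2) in DENND5A-KD cells at day 0, a log2 fold change of -1.16 ± 0.12 (SE, adjusted p = 5.62e-06). On inserts at day 4 it read 10.6 ± 0.367 (SD, n = 3) against 3.83 ± 0.658 (SD, n = 2), a log2 fold change of -1.28 ± 0.13 (adjusted p = 4.63e-06). AVL9 (ENSCAFG00000003143) read 23 ± 0.752 FPKM (SD, n = 4) in wild-type and 6.46 ± 1.07 (SD, n = 2) in AVL9-KD cells at day 0 (-1.70 ± 0.14, adjusted p = 1.33e-07). On day 4 of 2D culture wild-type cells had 21.7 ± 3.6 FPKM (SD, n = 3) and AVL9-KD cells 5.12 ± 1.74 FPKM (SD, n = 2), with a log2 fold change of -1.91 ± 0.15 (adjusted p = 8.19e-08). In each case, every knockdown library lay below every wild-type library. With limma fitted on these groups alone, the AVL9 difference at 2D day 4 had an adjusted p of 0.0695. DENND5A also rose in wild-type cells on inserts, by 0.82 ± 0.11 at day 4 and 1.14 ± 0.11 at day 11. AVL9 fell in 3D to 13.1 ± 1.92 FPKM (SD, n = 2) at day 8 (-0.77 ± 0.14, adjusted p = 0.000104). AVL9-KD cells held more DENND5A at day 0 (0.52 ± 0.12, adjusted p = 0.0075), a difference of 0.28 ± 0.13 that did not pass at 2D day 4 (adjusted p = 0.138).

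**Figure D2:**
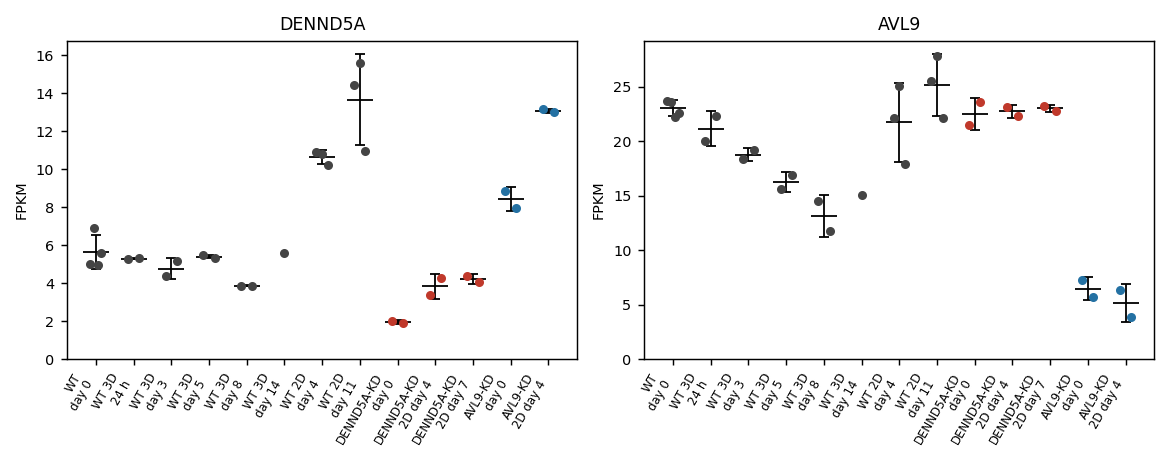
FPKM of DENND5A (left) and AVL9 (right) in each library by group, points for libraries and horizontal lines with bars for the mean and SD. DENND5A averaged 1.95 FPKM in DENND5A-KD and 5.62 in wild-type cells at day 0, and AVL9 6.46 in AVL9-KD and 23 in wild-type cells.

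After 24 h on matrigel, immediate early genes and YAP and TAZ targets fell. The first were also low in day 0 knockdown cells (list means -0.74 to -0.39), so wild-type day 0 may be high. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, went from 2.21 ± 1.51 (SD, n = 4) to 41 ± 0.22 (SD, n = 2) FPKM (3.85 ± 0.37). The quinone reductase NQO1 (1.69 ± 0.34), the heme oxygenase HMOX1 (1.38 ± 0.23), the glutathione peroxidase GPX2 (1.90 ± 0.37), and the oxidoreductase PTGR1 (1.48 ± 0.34) rose as well. So did pirin PIR (1.27 ± 0.28), the thioredoxin inhibitor TXNIP (1.29 ± 0.24) and the glycogen-targeting subunit PPP1R3C (1.30 ± 0.29). FOS, an AP-1 subunit, dropped from 151 ± 22.5 (SD, n = 4) to 14.1 ± 0.1 (SD, n = 2) FPKM (-3.32 ± 0.20). TIMP3, an inhibitor of metalloproteinases (-1.80 ± 0.38), and the muscle ankyrin repeat gene ANKRD1 (-2.11 ± 0.40) fell too. Of the 14 measured immediate early genes, 6 fell and none rose past the test, led by FOS, FOSB (-4.20 ± 0.28), EGR1 (-2.33 ± 0.20) and DUSP1 (-1.96 ± 0.23). There were 8 adjusted over the list alone (camera adjusted p = 3.34e-22, adjusted p = 0.000706 with an estimated correlation). Likewise 7 of 15 YAP and TAZ targets fell, led by AMOTL2 (-1.69 ± 0.21), CYR61 (-2.01 ± 0.29) and CTGF (-1.50 ± 0.22). This was 12 adjusted over the list alone (camera adjusted p = 1.56e-22, adjusted p = 0.0014 with an estimated correlation). In the cytoskeleton list 2 of 19 genes fell, including KRT80 (-1.12 ± 0.22). In all 5 passed adjusted over the list alone (camera adjusted p = 1.71e-07, adjusted p = 0.171 with an estimated correlation). In the TGF-beta and BMP list 2 of 13 fell, NOG (-1.42 ± 0.21) and INHBA (-0.97 ± 0.20). With the list adjusted alone 2 higher and 5 lower passed (camera adjusted p = 0.00111, adjusted p = 0.11 with an estimated correlation). None of the 18 mitosis genes passed (median 0.00, camera adjusted p = 0.414). With limma 140 of 11774 genes changed at 24 h, 74 higher and 66 lower. After quantile normalization 84 were higher and 136 lower. The count was 201 with the batch term and 114 without the 5 libraries. The count rested on single libraries, with 77 genes without day 0 replicate 3.

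Over 3D days 3, 5 and 8, several genes rose from day 0. PDZK1, a scaffold of apical transporters, went from 2.67 ± 2.07 (SD, n = 4) FPKM to 66.2 ± 20.2 (SD, n = 2), 186 ± 12.8 and 276 ± 65.8 at days 3, 5 and 8 (6.41 ± 0.87 at day 8). FXYD2, a regulatory subunit of the sodium pump (3.74 ± 0.59, 4.70 ± 0.59 and 5.20 ± 0.59), rose at each day. SAMD11 (4.78 ± 0.31) and the retinaldehyde reductase DHRS3 (4.83 ± 0.24) were higher at day 8. RBP4, the retinol carrier (3.90 ± 0.45), the phosphatase inhibitor PPP1R1B (4.29 ± 0.35) and RIPPLY1 (4.32 ± 0.70) were among the largest increases at day 3. At day 8 they included LBH (4.82 ± 0.35) and the matrix proteoglycan PODN (4.95 ± 0.38). CD24, a surface glycoprotein, was listed at 0 in all day 0 libraries, at 19.9 and 5.11 FPKM at day 3, 53 and 40.4 at day 5, and 163 and 51.8 at day 8.

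In the opposite direction, the intermediate filament gene VIM fell from 1590 ± 173 (SD, n = 4) FPKM to 54.4 ± 6.21 (SD, n = 2) by 3D day 8 (-4.84 ± 0.20). The collagen cross-linking enzyme LOX (-4.72 ± 0.35), the activin antagonist FST (-4.69 ± 0.53), the growth factor carrier FGFBP1 (-5.34 ± 0.61), and the prostaglandin synthase PTGS2 (-4.69 ± 0.35) fell too. So did the tryptophan-degrading enzyme IDO1 (-4.97 ± 0.55), the kinase DCLK1 (-4.33 ± 0.34) and FOSB (-4.39 ± 0.28). At earlier days CYR61 (-3.44 ± 0.29), TIMP3 (-3.21 ± 0.38) and KRT80 (-3.19 ± 0.22) at day 3, and FABP3 (-3.84 ± 0.51) and tissue factor F3 (-3.78 ± 0.18) at day 5, were among the largest decreases. Of 18 mitosis genes, 11 had fallen at day 3 and all 18 at days 5 and 8, with TPX2 (-2.44 ± 0.23), PLK1 (-2.21 ± 0.21) and CDC20 (-1.83 ± 0.17) at day 8. There were 18 adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.428 with an estimated correlation). DNA replication genes fell in the same way, 14, 17 and 18 of 18, led at day 8 by POLA1 (-2.60 ± 0.13) and UHRF1 (-2.22 ± 0.13). This was 18 adjusted over the list alone (camera adjusted p = 2.9e-07, adjusted p = 0.421 with an estimated correlation). Cholesterol synthesis genes fell in 9, 16 and 16 of 18 cases, including CYP51A1 (-1.69 ± 0.18) at day 8. There were 1 higher and 16 lower adjusted over the list alone (camera adjusted p = 0.000619, adjusted p = 0.562 with an estimated correlation). All but 1 of the 14 NF-kB and cytokine genes had fallen by day 8, among them TNFAIP3 (-2.59 ± 0.23), TNFAIP2 (-1.57 ± 0.15) and CSF2 (-3.59 ± 0.37). The number was 13 adjusted over the list alone (camera adjusted p = 0.000619, adjusted p = 0.426 with an estimated correlation). Of 14 immediate early genes 13 had fallen. There were 14 adjusted over the list alone (camera adjusted p = 1.9e-05, adjusted p = 0.392 with an estimated correlation). In the cytoskeleton list 16 of 19 fell and 2 rose at day 8, led by FLNA (-2.87 ± 0.14), ACTN1 (-2.68 ± 0.15) and TPM4 (-2.26 ± 0.15). On the list alone 2 higher and 16 lower passed (camera adjusted p = 0.000143, adjusted p = 0.421 with an estimated correlation). Of 15 YAP and TAZ targets 10 fell, led by F3 (-4.17 ± 0.18) and CYR61 (-3.83 ± 0.29). In all 11 passed adjusted over the list alone (camera adjusted p = 0.00257, adjusted p = 0.421 with an estimated correlation). Of 12 mesenchymal markers 7 fell and 1 rose, with SNAI2 (-2.26 ± 0.20) and THBS1 (-1.57 ± 0.25) beside VIM and LOX. These were 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.421 with an estimated correlation). Of fibroblast and endothelial genes, FBLN1 (-2.21 ± 0.23) and FLT1 (-2.91 ± 0.15) fell too.

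Primary cilium genes rose in 15 of 22 cases at each of 3D days 3, 5 and 8, with 3 lower at day 8. The day 8 risers included TMEM67 (1.53 ± 0.11) and BBS2 (1.27 ± 0.11). The numbers were 15 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000318, adjusted p = 0.421 with an estimated correlation). Among 13 distal nephron transport genes, 8 rose and 1 fell at day 8, led by CA2 (3.02 ± 0.25), FXYD2 (5.20 ± 0.59) and KCNJ16 (2.21 ± 0.29). With the list adjusted alone 8 higher and 1 lower passed (camera adjusted p = 0.00273, adjusted p = 0.421 with an estimated correlation). Ribosomal protein genes rose in 11, 13 and 15 of 17 cases at days 3, 5 and 8. In all 16 passed adjusted over the list alone (camera adjusted p = 1.43e-05, adjusted p = 0.428 with an estimated correlation). Interferon-stimulated genes fell in 10 of 19 cases at day 8, with CMPK2 (-3.28 ± 0.21), IFIH1 (-1.27 ± 0.10) and OAS2 (-1.78 ± 0.19). The number was 10 adjusted over the list alone (camera adjusted p = 0.029, adjusted p = 0.62 with an estimated correlation, adjusted p = 0.053 with the batch term). Polarity complex genes fell in 9 of 11 cases and rose in 1, led by MARK2 (-1.22 ± 0.11), LLGL2 (-1.11 ± 0.11) and PARD3 (-0.87 ± 0.11). There were 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.62 with an estimated correlation, adjusted p = 0.0516 with the batch term). Junction genes went both ways. In the tight junction list 5 rose and 8 fell of 16 at day 8, such as CLDN2, a pore-forming claudin (3.00 ± 0.30), and TJP1, the scaffold ZO-1 (-1.40 ± 0.12). On the list alone 5 higher and 8 lower passed (camera adjusted p = 0.682).

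With limma 6009 of 11774 genes differed from day 0 at 3D day 3 (3294 higher and 2715 lower), 6787 at day 5 (3109 and 3678) and 7389 at day 8 (2911 and 4478). The counts were 6374, 6969 and 7673 with the batch term, and 6686 at day 5 without the 5 libraries. At day 8 the median fold change of all genes was -0.13 and 39.4% of calls were higher. After median-ratio scaling these came to 0.07 and 54.6%. The majority also turned at day 3 after quantile normalization (3067 higher and 3340 lower) and at day 5 after median-ratio scaling (4014 and 3273). SNORA58, a small nucleolar RNA, was called lower at day 3, where it was listed at 0 in both libraries. The day 0 libraries read 78.6, 3.63, 9.01 and 3.72 FPKM.

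3D day 8 was also set against the 24 h cysts. PDZK1 (6.13 ± 1.00), LBH (5.25 ± 0.40), PODN (4.92 ± 0.44), and the organic cation transporter SLC22A2 (4.64 ± 0.39) were higher. VIM went from 1367 ± 32.7 (SD, n = 2) to 54.4 ± 6.21 (SD, n = 2) FPKM (-4.63 ± 0.23). FGFBP1 (-5.43 ± 0.70), PTGS2 (-4.14 ± 0.40), the interleukin 33 receptor IL1RL1 (-4.13 ± 0.34), the neuronal cytoskeleton gene DPYSL3 (-3.99 ± 0.27) and the reductase DHRS2 (-3.92 ± 0.57) were lower. TMSB10 was called lower (-5.64 ± 2.08), but its 2 day 8 libraries read 0 and 1692 FPKM, the first being 1 of the 5 libraries that stood apart. FAM195A, also called lower, was listed at 0 in both. All 18 mitosis genes fell, led by CDC20 (-1.87 ± 0.20) and PLK1 (-2.23 ± 0.24). In all 18 passed adjusted over the list alone (camera adjusted p = 1.68e-06, adjusted p = 0.569 with an estimated correlation). All 18 DNA replication genes fell, led by POLA1 (-2.25 ± 0.15) and UHRF1 (-2.15 ± 0.15). The number was 18 adjusted over the list alone (camera adjusted p = 1.07e-07, adjusted p = 0.569 with an estimated correlation). Of 18 cholesterol synthesis genes 16 fell. There were 16 adjusted over the list alone (camera adjusted p = 0.000452, adjusted p = 0.569 with an estimated correlation). Cilium genes were 13 higher and 4 lower of 22, led by TMEM67 (1.34 ± 0.12). These were 13 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.000122, adjusted p = 0.569 with an estimated correlation). The count was 6331 of 11774 genes, 2038 higher and 4293 lower at a median of -0.19. It was 6613 with the batch term. After quantile normalization, which brought the median to -0.02, 3116 were higher and 3398 lower.

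The single 3D day 14 library has no replicate, so groups were not tested, and the percentiles given describe this library only. It listed VIM at 29 FPKM and PDZK1 at 453. The day 8 libraries read 50 and 58.8 for VIM and 323 and 230 for PDZK1. Against the day 0 mean, 1480 genes were at least 2-fold higher and 1375 at least 2-fold lower. The median of the mitosis list was -2.06 against day 0 and that of the NF-kB list -1.38, both below all of 10000 random lists matched on size and mean expression (percentile 0). Distal nephron transport lay at 0.96 (percentile 99.8) and primary cilium at 0.57 (percentile 99.7). Against day 8 replicate 1, which also stood apart, the mitosis list lay at -0.33 (percentile 0) and the immediate early list at 0.42 (percentile 100), and FOS read 30 FPKM against 11.5.

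On transwell inserts, compared with day 0, PDZK1 reached 241 ± 111 (SD, n = 3) FPKM at day 4 and 154 ± 31.7 (SD, n = 3) at day 11 (6.13 ± 0.77 and 5.57 ± 0.77). CDH16, kidney-specific cadherin, went from 0.22 ± 0.102 (SD, n = 4) to 51.8 ± 13.4 (SD, n = 3) and 37.8 ± 2.16 (5.41 ± 0.32 at day 4). PODN (5.80 ± 0.34), the selenium carrier SEPP1 (4.81 ± 0.51), the basement membrane collagen COL18A1 (4.28 ± 0.33), FXYD2 (4.18 ± 0.53) and TXNIP (4.06 ± 0.21) rose at day 4. NQO1 fell at both days (-3.26 ± 0.30 and -3.04 ± 0.30), as it did at 3D days 5 and 8 (-1.60 ± 0.34 and -1.57 ± 0.34) after its rise at 24 h. The chemokine CCL2 (-3.40 ± 0.61), the AP-1 subunit FOSL1 (-2.58 ± 0.26), the cytokine CSF2 (-2.16 ± 0.32) and the CTP synthase CTPS1 (-2.14 ± 0.14) fell by day 11.

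All 18 mitosis genes fell at 2D day 4, with CDC20 (-2.40 ± 0.15), PLK1 (-2.61 ± 0.18) and UBE2C (-2.92 ± 0.21). In all 18 passed adjusted over the list alone (camera adjusted p = 5.63e-12, adjusted p = 0.298 with an estimated correlation). All 18 DNA replication genes fell as well, led by UHRF1 (-2.42 ± 0.12) and MCM5 (-2.75 ± 0.14). The number was 18 adjusted over the list alone (camera adjusted p = 7.9e-13, adjusted p = 0.224 with an estimated correlation). At day 11, 18 of 18 mitosis genes were lower. There were 18 adjusted over the list alone (camera adjusted p = 7.62e-10, adjusted p = 0.359 with an estimated correlation). So were 18 of 18 DNA replication genes. This was 18 adjusted over the list alone (camera adjusted p = 9.25e-13, adjusted p = 0.227 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 18 cases at day 11 and in 17 at day 4. In all 17 passed adjusted over the list alone (camera adjusted p = 2.09e-05, adjusted p = 0.552 with an estimated correlation). Immediate early genes fell in 12 of 14 cases at day 11 and in 13 at day 4. The number was 13 adjusted over the list alone (camera adjusted p = 1.03e-05, adjusted p = 0.224 with an estimated correlation). Primary cilium genes rose in 14 of 22 cases on either day and 1 fell at day 4, the risers at day 4 including BBS4 (1.29 ± 0.10) and PKHD1 (2.19 ± 0.17). The numbers were 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000208, adjusted p = 0.298 with an estimated correlation). Distal nephron transport genes rose in 8 of 13 cases at both days and none fell past the test, with KCNJ16 (3.28 ± 0.26) and CFTR (2.33 ± 0.23) at day 4. This was 8 adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.298 with an estimated correlation). In the basement membrane list 12 of 19 genes rose and 2 fell at day 4, with COL18A1, AGRN (1.73 ± 0.16) and COL4A1 (2.41 ± 0.35) among the risers. With the list adjusted alone 12 higher and 2 lower passed (camera adjusted p = 0.017, adjusted p = 0.741 with an estimated correlation). Interferon-stimulated genes rose in 9 of 19 cases at day 4. The number was 9 adjusted over the list alone (camera adjusted p = 0.0603). At day 11, 17 of them rose, led by BST2 (1.86 ± 0.16), MX1 (3.38 ± 0.34) and IFI44L (1.55 ± 0.18). There were 17 adjusted over the list alone (camera adjusted p = 1.46e-05, adjusted p = 0.419 with an estimated correlation). Without the 5 libraries, 5 interferon-stimulated genes were higher and 1 lower at day 4. DENN family and RAB genes rose in 12 of 23 cases and 2 fell at day 11, with DENND5A at 1.14 ± 0.11 and SBF2 at 0.92 ± 0.11. There were 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.631 with an estimated correlation). Apical membrane genes rose in 9 of 12 cases at day 11, with TMEM27, collectrin (2.53 ± 0.23), and MUC1 (0.70 ± 0.17) beside PDZK1. In all 9 passed adjusted over the list alone (camera adjusted p = 0.0366, adjusted p = 0.549 with an estimated correlation). With limma 7055 of 11774 genes changed at day 4 (3572 higher and 3483 lower) and 6587 at day 11 (3792 higher and 2795 lower). The day 4 count was 7398 with the batch term and 6330 without the 5 libraries, and the day 11 count 6735 and 6261. Quantile normalization turned the majorities, to 3605 higher and 3786 lower at day 4 and 3305 and 3532 at day 11.

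**Figure D3:**
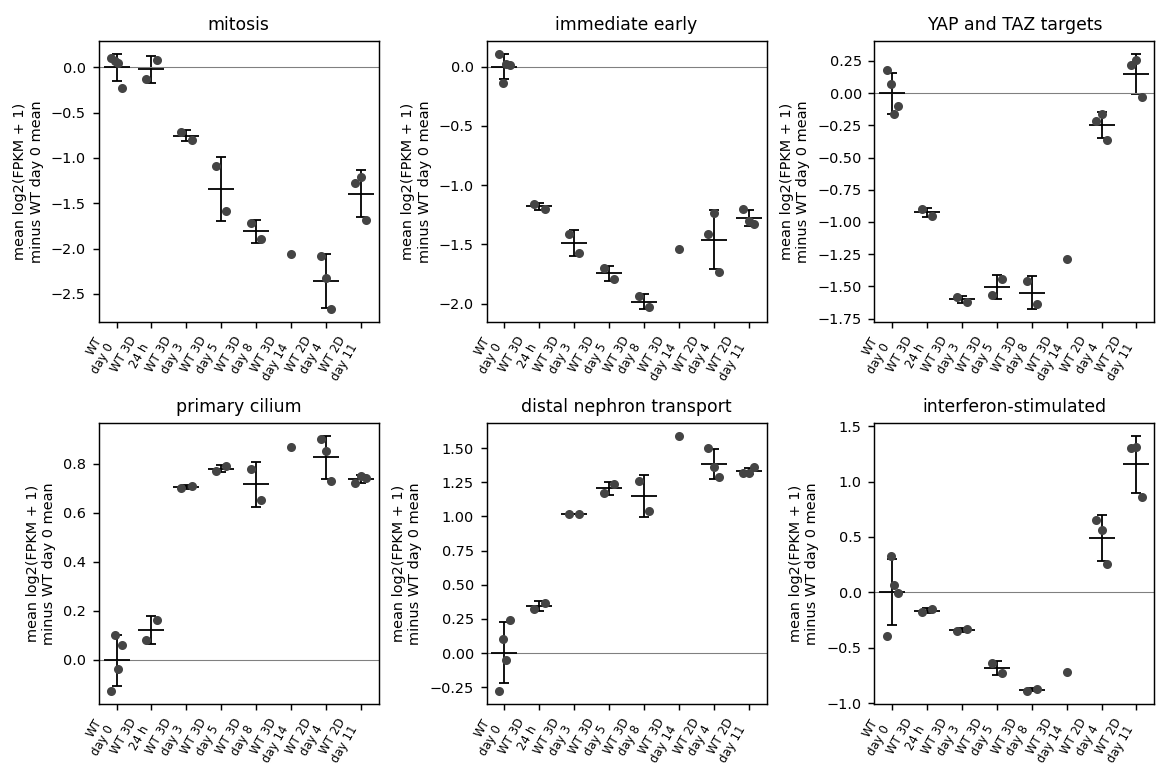
Mean log2(FPKM + 1) of the genes of 6 lists minus the wild-type day 0 mean, by group of wild-type libraries, with points for libraries and lines with bars for the mean and SD. The mitosis mean lay between -2.67 and -2.08 in 2D day 4 libraries and between -1.69 and -1.21 at day 11, and the interferon-stimulated mean between 0.86 and 1.31 at 2D day 11 and between -0.89 and -0.87 at 3D day 8.

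Between 2D day 4 and day 11, MT1E went from 23.1 ± 2.55 (SD, n = 3) to 113 ± 48.3 (SD, n = 3) FPKM (2.16 ± 0.42), and MT1X rose by 1.24 ± 0.29. The lysosomal protease CTSK (1.58 ± 0.34), the endolysosomal glycoprotein GPNMB (1.78 ± 0.34), CCNA2 (1.26 ± 0.26) and KNSTRN, a kinetochore gene (1.18 ± 0.21), rose. ISG15, a ubiquitin-like modifier, rose by 1.37 ± 0.35 with an adjusted p = 0.0474, which was 0.059 with the batch term. SCG5, a chaperone of prohormone convertase (-1.04 ± 0.23), JCHAIN, the immunoglobulin joining chain (-0.81 ± 0.18), and SESN2, a stress-induced sestrin (-0.64 ± 0.12), fell. Of the 18 mitosis genes 16 rose, led by BIRC5 (1.04 ± 0.18), KIF20A (1.35 ± 0.25) and CDC20 (0.82 ± 0.16). The number was 18 adjusted over the list alone (camera adjusted p = 4.98e-20, adjusted p = 0.209 with an estimated correlation). DNA replication genes rose in 9 of 18 cases, led by MCM5 (0.91 ± 0.15) and UHRF1 (0.64 ± 0.12). There were 17 adjusted over the list alone (camera adjusted p = 1.96e-14, adjusted p = 0.209 with an estimated correlation). Among 19 interferon-stimulated genes 6 rose, led by IFIH1 (0.59 ± 0.10), MX2 (0.93 ± 0.16) and CMPK2 (0.90 ± 0.20). This was 14 adjusted over the list alone (camera adjusted p = 1.07e-10, adjusted p = 0.248 with an estimated correlation). The count was 245 of 11774 genes, 224 higher and 21 lower. It was 386 with the batch term and 176 without the 5 libraries. After quantile normalization 375 changed, 254 higher and 121 lower, and on these groups alone 2 did. Single libraries set the count, with 1 gene without day 4 replicate 3, 0 without day 11 replicate 1 or 2 and 590 without day 11 replicate 3. With limma on all libraries 1808 genes had an unadjusted p under 0.05.

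Cysts at 3D days 3, 5 and 8 were set against 2D days 4 and 11, which compares gel and insert although the days differ. ID3 and ID4, inhibitors of basic helix-loop-helix factors, were higher in 3D (3.01 ± 0.16 and 2.42 ± 0.23). So were RBP4 (2.90 ± 0.30), the matrix protein TGFBI (2.61 ± 0.14), PPP1R1B (2.69 ± 0.23), SAMD11 (2.28 ± 0.20), CYP1A1 (2.46 ± 0.24) and PIR (2.07 ± 0.19). ID3 read 198 ± 9.1 (SD, n = 2) FPKM at 3D day 3 and 19.4 ± 2.53 (SD, n = 3) at 2D day 4. The growth factor TGFB2 (-3.19 ± 0.19), the basement membrane collagens COL4A1 (-3.14 ± 0.27) and COL4A2 (-3.02 ± 0.27), and NREP (-2.91 ± 0.34) were lower. CYR61 (-2.75 ± 0.20), FGFBP1 (-3.03 ± 0.40), ISG15 (-2.71 ± 0.25) and IDO1 (-2.61 ± 0.37) were lower too. All 19 genes of the basement membrane list were lower in 3D, with HSPG2, perlecan, at -1.59 ± 0.11. In all 19 passed adjusted over the list alone (camera adjusted p = 4.02e-07, adjusted p = 0.253 with an estimated correlation). All 19 interferon-stimulated genes were lower, led by CMPK2 (-2.47 ± 0.14) and IFIH1 (-1.17 ± 0.07). The number was 19 adjusted over the list alone (camera adjusted p = 1.02e-09, adjusted p = 0.253 with an estimated correlation). YAP and TAZ targets were lower in 14 of 15 cases and higher in 1, led by PTPN14 (-1.73 ± 0.09) and TGFB2 (-3.19 ± 0.19). On the list alone 1 higher and 14 lower passed (camera adjusted p = 1.72e-07, adjusted p = 0.253 with an estimated correlation). Cytoskeleton genes were lower in 16 of 19 and higher in 1, among them TLN1 (-1.36 ± 0.07) and MYH9 (-1.80 ± 0.11). These were 1 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.36e-06, adjusted p = 0.253 with an estimated correlation). Polarity genes were lower in 10 of 11 cases, led by PARD3 (-0.78 ± 0.07) and MARK2 (-0.75 ± 0.07). In all 10 passed adjusted over the list alone (camera adjusted p = 0.000768, adjusted p = 0.337 with an estimated correlation). Adherens junction and desmosome genes were lower in 14 of 16 with 1 higher, led by CDH16 (-2.44 ± 0.24) and CDH1, E-cadherin (-1.03 ± 0.11). The numbers were 1 higher and 14 lower adjusted over the list alone (camera adjusted p = 0.000413, adjusted p = 0.337 with an estimated correlation). Glycolysis and hypoxia genes were lower in 12 of 16 cases, led by EGLN3 (-1.93 ± 0.21) and HK1 (-0.96 ± 0.12). There were 12 adjusted over the list alone (camera adjusted p = 0.00297, adjusted p = 0.41 with an estimated correlation). DENN family and RAB genes were lower in 19 of 23 with 1 higher, led by DENND5A (-1.21 ± 0.08). With the list adjusted alone 1 higher and 19 lower passed (camera adjusted p = 0.000331, adjusted p = 0.337 with an estimated correlation). Ribosomal protein genes were higher in 15 of 17 cases. In all 15 passed adjusted over the list alone (camera adjusted p = 8.17e-08, adjusted p = 0.337 with an estimated correlation). Oxidative phosphorylation genes were higher in 11 of 15, with COX4I1 at 0.73 ± 0.11. The number was 11 adjusted over the list alone (camera adjusted p = 0.000328, adjusted p = 0.364 with an estimated correlation). The mitochondrial genome made up 11 to 27.8% of FPKM in these 3D libraries and 8.9 to 16.2% in the 2D ones. Mitosis genes were higher in 13 of 18, with BIRC5 at 1.04 ± 0.13. There were 13 adjusted over the list alone (camera adjusted p = 1.62e-05, adjusted p = 0.41 with an estimated correlation). DNA replication genes were higher in 16 of 18, led by GINS2 (0.90 ± 0.12) and MCM5 (0.76 ± 0.10). There were 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.98e-05, adjusted p = 0.337 with an estimated correlation). The days differed, mitosis means relative to day 0 being -0.80 to -0.71 at 3D day 3, -1.90 to -1.72 at 3D day 8, -2.67 to -2.08 at 2D day 4 and -1.69 to -1.21 at 2D day 11, and those of DNA replication -0.82 to -0.70, -1.52 to -1.50, -2.13 to -1.71 and -1.49 to -1.20. The count was 6696 of 11774 genes, 2602 higher and 4094 lower. It was 7041 with the batch term. After quantile normalization 3573 were higher and 3605 lower.

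Changes from day 0 in 3D and 2D shared the day 0 libraries. Genes called at both 3D day 8 and 2D day 4 were higher in both in 2166 cases, lower in both in 2799 and opposite in 261. Independent lists would share 883.1 and 1324.7. Simulated unchanged groups have few calls, so 0 shared is no test. Fold changes correlated across genes with r of 0.78 and a covariance of 0.567, against 0.38 and 0.0199 simulated. With the 4 controls split so that each comparison had its own pair, means over 6 splits were 1877 higher and 2413 lower in both, with r of 0.73 and a covariance of 0.544. For 3D day 8 and 2D day 11 the values were 2117 and 2295 in the same direction and 417 opposite. They had r of 0.72 and a covariance of 0.454 (simulated 0.38 and 0.0201), and 0.66 and 0.431 with split controls. PDZK1, FXYD2 and PODN were among the genes higher in all 3 comparisons.

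At day 0, the basement membrane collagen COL4A1 read 5.94 ± 3.7 (SD, n = 4) FPKM in wild-type and 39 ± 0.652 (SD, n = 2) in DENND5A-KD cells (2.69 ± 0.40). Its partner COL4A2 was higher by 2.17 ± 0.41. The iron reductase CYBRD1 (2.59 ± 0.38), the hypoxia-inducible factor subunit EPAS1 (2.51 ± 0.15), and the TEAD cofactor VGLL3 (2.41 ± 0.34) were higher. CLDN2 went from 14.7 ± 6.49 (SD, n = 4) to 0.59 ± 0.0384 (SD, n = 2) FPKM (-3.19 ± 0.30). The calcium-binding S100A4 (-3.71 ± 0.94), the muscarinic receptor CHRM4 (-2.91 ± 0.33), IL1RL1 (-2.63 ± 0.29), FOSB (-2.59 ± 0.28), PRR15L (-2.56 ± 0.37) and FXYD2 (-2.18 ± 0.59) were lower. Among 19 interferon-stimulated genes 12 were higher, or 9 without the 5 libraries, led by IFIH1 (1.46 ± 0.10), IFIT2 (1.27 ± 0.17) and IFIT1 (1.09 ± 0.19). In all 17 passed adjusted over the list alone (camera adjusted p = 1.17e-16, adjusted p = 0.188 with an estimated correlation). Of 14 immediate early genes 3 were lower, FOS (-1.84 ± 0.20), FOSB (-2.59 ± 0.28) and EGR1 (-1.21 ± 0.20). The number was 3 adjusted over the list alone (camera adjusted p = 8.04e-05, adjusted p = 0.236 with an estimated correlation). In the cholesterol synthesis list 2 of 18 were lower, including FDFT1 (-1.58 ± 0.38), or 1 without the 5 libraries. There were 4 adjusted over the list alone (camera adjusted p = 0.00115, adjusted p = 0.667 with an estimated correlation). Unfolded protein and integrated stress genes were lower in 4 of 17 cases, led by ATF4 (-0.81 ± 0.17) and HERPUD1 (-0.69 ± 0.15). This was 4 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.645 with an estimated correlation). With limma 650 of 11774 genes differed, 385 higher and 265 lower. The count was 701 with the batch term and 622 without the 5 libraries. Without DENND5A-KD line 1 the count was 288 and without line 2 it was 207.

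AVL9-KD cells at day 0 also showed higher EPAS1 (3.04 ± 0.15) and VGLL3 (2.55 ± 0.34). The protease inhibitor SPINK6 went from 2.98 ± 2.08 (SD, n = 4) to 38.5 ± 19.4 (SD, n = 2) FPKM (3.44 ± 0.44). The metalloreductase STEAP2 (3.06 ± 0.25), the complement regulator CD55 (2.92 ± 0.30), N-cadherin CDH2 (2.86 ± 0.46) and IGDCC4 (2.75 ± 0.28) were higher. The transcription factor MSC read 13.6 and 2.61 FPKM in the knockdown lines and was listed at 0 in 3 of 4 wild-type libraries. FOS read 18.8 ± 3.6 (SD, n = 2) FPKM against 151 ± 22.5 (SD, n = 4) in wild type (-2.94 ± 0.20). FOSB (-4.11 ± 0.28), EGR1 (-2.65 ± 0.20), and CLDN2 (-3.82 ± 0.30) were lower. So were CHRM4 (-3.42 ± 0.33), PRR15L (-2.71 ± 0.37) and the proteoglycan VCAN (-3.52 ± 0.59). SNORA58 was listed at 0 in all knockdown libraries at day 0. Of 15 p53 targets 9 were higher, led by CCNG1 (1.35 ± 0.15), BAX (0.94 ± 0.14) and CDKN1A (1.53 ± 0.29). On the list alone 9 higher and 1 lower passed (camera adjusted p = 0.00907, adjusted p = 0.835 with an estimated correlation). Of 14 NF-kB and cytokine genes 5 were higher, led by LIF (1.17 ± 0.26), CSF2 (1.63 ± 0.37) and ICAM1 (1.03 ± 0.29). The number was 9 adjusted over the list alone (camera adjusted p = 0.00907, adjusted p = 0.835 with an estimated correlation). Immediate early genes were lower in 4 of 14 cases and higher in 1. These were 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.000905, adjusted p = 0.739 with an estimated correlation). In the tight junction list 3 of 16 were lower, led by CLDN2 and CGN (-0.61 ± 0.12), and 1 higher. The numbers were 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00907, adjusted p = 0.835 with an estimated correlation). In the distal nephron list 3 of 13 were lower and 1 higher, with SLC12A2 (-0.60 ± 0.18) and SCNN1B (1.35 ± 0.32) as examples. With the list adjusted alone 1 higher and 3 lower passed (camera adjusted p = 0.019, adjusted p = 0.835 with an estimated correlation). With limma 2118 of 11774 genes differed, 1578 higher and 540 lower at a median of 0.11. The count was 2745 with the batch term and 2667 without the 5 libraries. After quantile normalization (median -0.01) 899 were higher and 956 lower. Without wild-type replicate 4 the count was 1320 and without AVL9-KD line 1 it was 745. S100A4 read 0.832 FPKM in line 1 and 62.6 in line 4.

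The knockdowns shared changes at day 0, against the same wild-type libraries. In both, 239 genes were higher and 115 lower, and 12 went opposite ways. Independent lists would share 51.6 and 12.2. The correlation of fold changes across genes was 0.52 with a covariance of 0.0898, against 0.34 and 0.0202 in the simulation. With split controls 153 and 54 genes were shared, with r of 0.34 and a covariance of 0.0663. The shared genes included FAM171B (2.16 ± 0.14 and 2.22 ± 0.14), the peptidase DPP4 (1.94 ± 0.22 and 2.03 ± 0.22) and CDH2 (2.09 ± 0.46 and 2.86 ± 0.46) on the higher side. CLDN2, CHRM4 and the tetraspanin TSPAN5 (-1.94 ± 0.20 and -2.16 ± 0.20) were lower in both. At 2D day 4 the knockdowns shared 284 higher and 137 lower genes with 22 opposite (121.8 and 15.9 for independent lists). There r was 0.48 and the covariance 0.0936 (simulated 0.39 and 0.0258). Over all genes, 57.5% had the same direction there, below the 63.1% simulated, against 64% and 60.8% at day 0. The 3 wild-type libraries of that day cannot be split into pairs, so part of the excess may come from the shared controls. PDZK1, TSPAN5 and TMEM27 were lower in both there, and CFTR too (-2.01 ± 0.27 and -1.95 ± 0.27).

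At 2D day 4, PDZK1 read 241 ± 111 (SD, n = 3) FPKM in wild-type and 16.8 ± 14.2 (SD, n = 2) in DENND5A-KD cells (-3.93 ± 0.92). The nuclear receptor HNF4A (-2.79 ± 0.51), collectrin TMEM27 (-2.56 ± 0.28) and the tetraspanins TSPAN5 (-2.96 ± 0.21) and TSPAN1 (-2.56 ± 0.52) were lower too, as were the matrix protein VWA2 (-2.88 ± 0.34) and the GABA receptor subunit GABRA3 (-2.90 ± 0.59). The glucan receptor CLEC7A (2.63 ± 0.32), FSTL1, a secreted follistatin-like protein (2.53 ± 0.29), the kinase inhibitor CDKN2B (2.38 ± 0.53), and TP53I11 (2.40 ± 0.30) were higher. Of 18 mitosis genes 17 were higher, or 16 without the 5 libraries, led by BIRC5 (1.48 ± 0.21), PLK1 (1.44 ± 0.22), CDC20 (1.19 ± 0.18) and KIF11 (1.22 ± 0.20). The number was 18 adjusted over the list alone (camera adjusted p = 3.46e-20, adjusted p = 0.205 with an estimated correlation). DNA replication genes were higher in 15 of 18 cases, or 14 without them, led by UHRF1 (1.30 ± 0.14), MCM5 (1.49 ± 0.17) and CDT1 (1.20 ± 0.16). There were 16 adjusted over the list alone (camera adjusted p = 6.72e-16, adjusted p = 0.205 with an estimated correlation). Interferon-stimulated genes were higher in 5 of 19 cases, led by IFIH1 (1.13 ± 0.11), IFIT2 (1.20 ± 0.18) and IFIT1 (1.25 ± 0.20). This was 5 adjusted over the list alone (camera adjusted p = 3.4e-05, adjusted p = 0.525 with an estimated correlation). Wnt response genes were higher in 3 of 9, NOTUM (1.46 ± 0.16), SP5 (0.78 ± 0.19) and ZNRF3 (0.60 ± 0.19). In all 3 passed adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.217 with an estimated correlation). Cilium genes were lower in 2 of 22 cases, IFT88 and PKHD1 (-0.94 ± 0.21). The number was 2 adjusted over the list alone (camera adjusted p = 0.033, adjusted p = 0.724 with an estimated correlation). In the distal nephron list 4 of 13 were lower, including CA2 (-0.94 ± 0.26) and KCNJ16 (-1.05 ± 0.31), or 2 without the 5 libraries. There were 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.231). With limma 1334 of 11774 genes differed, 652 higher and 682 lower. The count was 1358 with the batch term and 982 without the 5 libraries. It was 2069 after quantile normalization (1059 higher and 1010 lower), 97 on these groups alone and 416 without DENND5A-KD line 1.

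**Figure D4:**
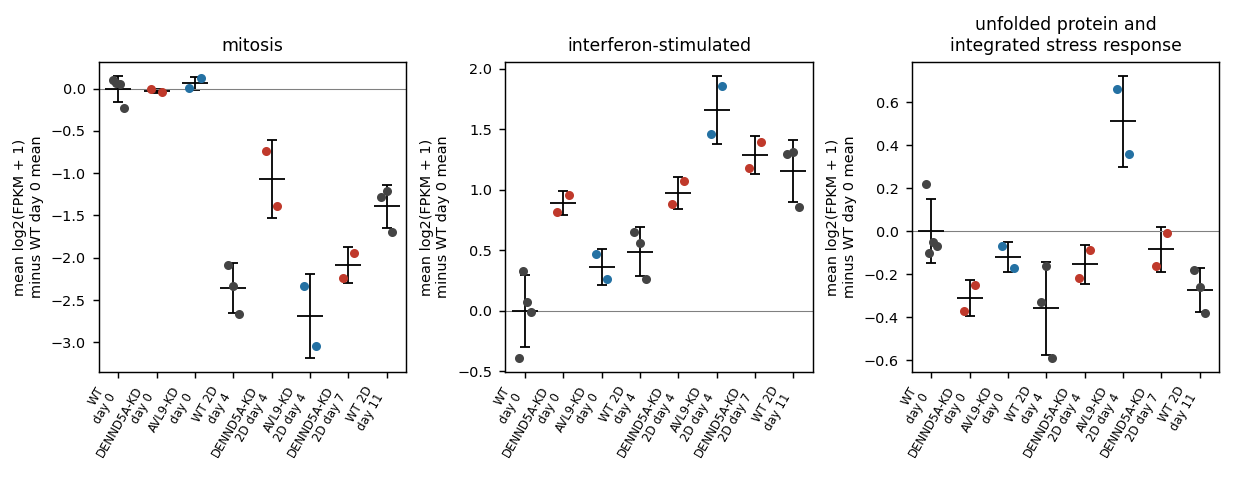
Mean log2(FPKM + 1) of the genes of 3 lists minus the wild-type day 0 mean, in wild-type and knockdown libraries at day 0 and on inserts, with points for libraries and lines with bars for the mean and SD. At 2D day 4 the mitosis mean lay between -1.39 and -0.74 in DENND5A-KD, between -2.67 and -2.08 in wild-type and between -3.04 and -2.34 in AVL9-KD libraries.

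AVL9-KD cells at 2D day 4 were compared with wild type in the same way. The reductase DHRS2 read 3.88 ± 2 (SD, n = 3) FPKM in wild type and 82.6 ± 54.2 (SD, n = 2) in the knockdown (4.00 ± 0.52). The chemokine CCL5 (2.74 ± 0.45), the Notch regulator DTX4 (2.79 ± 0.35), and RND3 (2.69 ± 0.22) were higher. So were the transglutaminase TGM2 (2.67 ± 0.26), the actin-binding TAGLN (2.65 ± 0.38) and the exonuclease ISG20 (2.50 ± 0.36). PDZK1 read 47.9 ± 65.7 (SD, n = 2) FPKM (-3.88 ± 0.92), with the 2 lines at 1.46 and 94.3. TSPAN5 (-3.53 ± 0.21), IL1RL1 (-2.47 ± 0.31), the guidance molecule SLIT3 (-2.25 ± 0.29) and TMEM27 (-2.19 ± 0.28) were lower. SNORA14 was called higher, being listed at 0 in the wild-type libraries of that day and at 6.79 and 12.2 FPKM in the knockdown. Of 19 interferon-stimulated genes 17 were higher, led by IFIH1 (1.44 ± 0.11), OASL (1.46 ± 0.14), DDX58 (1.67 ± 0.19) and CMPK2 (1.77 ± 0.22). This was 18 adjusted over the list alone (camera adjusted p = 9.04e-10, adjusted p = 0.494 with an estimated correlation). Unfolded protein and integrated stress genes were higher in 11 of 17 cases, led by PSAT1 (2.05 ± 0.22), DDIT4 (2.21 ± 0.29) and TRIB3 (2.16 ± 0.32). In all 11 passed adjusted over the list alone (camera adjusted p = 7.97e-05, adjusted p = 0.494 with an estimated correlation). The p53 targets were higher in 10 of 15, led by CDKN1A (1.88 ± 0.31), AEN (1.38 ± 0.25) and PLK2 (1.70 ± 0.31). The number was 11 adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.572 with an estimated correlation). Of 14 immediate early genes 10 were higher, led by DUSP6 (1.53 ± 0.17), MYC (1.35 ± 0.22) and JUNB (1.04 ± 0.18). There were 10 adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.494 with an estimated correlation). NF-kB and cytokine genes were higher in 6 of 14 cases, led by CCL5 and CXCL10 (1.44 ± 0.29). This was 9 adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.902 with an estimated correlation). Mitosis genes lay lower relative to other genes (median -0.36), none passing alone (camera adjusted p = 1.24e-06, adjusted p = 0.786 with an estimated correlation). With limma 2474 of 11774 genes differed, 2199 higher and 275 lower at a median of 0.19. The count was 3328 with the batch term and 2767 without the 5 libraries. After quantile normalization (median -0.01) 1100 were higher and 973 lower. On these groups alone 25 differed, and leaving out wild-type replicate 3 or AVL9-KD line 1 gave 1298 and 1184. VCAN read 10 FPKM in line 1 and 157 in line 4.

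The interaction asked whether a knockdown's difference from wild type changed between day 0 and 2D day 4. For DENND5A-KD, CLEC7A (3.15 ± 0.44), TP53I11 (2.51 ± 0.41), CENPH (1.92 ± 0.30), FOS (2.53 ± 0.28) and FOSB (2.90 ± 0.41) shifted upward. So did CHRM4 (2.64 ± 0.47), IL1RL1 (1.97 ± 0.42) and CLDN2 (2.42 ± 0.43). CLDN2 stood at 14.7 ± 6.49 (SD, n = 4) FPKM in wild-type and 0.59 ± 0.0384 (SD, n = 2) in knockdown cells at day 0. At 2D day 4 these were 87.4 ± 16.4 (SD, n = 3) and 51.8 ± 18.8 (SD, n = 2). VWA2 (-2.66 ± 0.47), TMEM27 (-2.56 ± 0.38), CSF2 (-2.48 ± 0.53), COL4A1 (-2.46 ± 0.58) and RASL11A (-2.17 ± 0.31) shifted downward. So did the endocytic adaptor DAB2 (-2.07 ± 0.41) and the netrin NTN4 (-2.03 ± 0.40). Mitosis genes shifted upward in 14 of 18 cases, led by BIRC5 (1.59 ± 0.28), CDC20 (1.11 ± 0.25) and MKI67 (1.73 ± 0.39), or in 8 without the 5 libraries. In all 18 passed adjusted over the list alone (camera adjusted p = 4.14e-23, adjusted p = 0.0919 with an estimated correlation). DNA replication genes did in 8 of 18, led by MCM5 (1.52 ± 0.23) and UHRF1 (1.24 ± 0.19). The number was 15 adjusted over the list alone (camera adjusted p = 4.2e-20, adjusted p = 0.0576 with an estimated correlation). Immediate early genes shifted upward in 3 of 14 cases, FOS, FOSB and EGR1 (1.78 ± 0.29). There were 6 adjusted over the list alone (camera adjusted p = 6.54e-09, adjusted p = 0.0576 with an estimated correlation). Wild-type FOS was itself 151 ± 22.5 (SD, n = 4) FPKM at day 0 and 20.8 ± 2.88 (SD, n = 3) at 2D day 4. With limma 215 of 11774 genes had an interaction, 135 upward and 80 downward. The count was 301 with the batch term and 157 without the 5 libraries, and 436 with the lines as a block. Without wild-type day 0 replicate 3 it was 118 and without wild-type 2D day 4 replicate 3 it was 112. Leaving out knockdown lines 1 or 2 gave 79 and 59 at day 0, and 45 and 419 at 2D day 4. Fitting these groups alone gave 74.

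For AVL9-KD the interaction was led by immediate early genes, with EGR1 (3.67 ± 0.29), FOS (3.56 ± 0.28) and FOSB (4.24 ± 0.41) shifting upward. EGR1 read 111 ± 17.2 (SD, n = 4) FPKM in wild-type and 16.7 ± 0.362 (SD, n = 2) in knockdown cells at day 0. At 2D day 4 it was 55.8 ± 12.5 (SD, n = 3) and 112 ± 10.8 (SD, n = 2). FOS read 127 to 179 FPKM in the wild-type day 0 libraries and 11.5 to 48.3 in all others. PRR15L (2.78 ± 0.54), the glutathione-degrading CHAC1 (2.77 ± 0.53), DTX4 (2.41 ± 0.48), the growth factor EGF (2.41 ± 0.28) and FGF21, a stress-induced hormone (2.39 ± 0.37), also shifted upward. TMEM27 (-2.17 ± 0.38), SLIT3 (-2.11 ± 0.41), RASL11A (-1.79 ± 0.31), TSPAN5 (-1.37 ± 0.29) and UBASH3B (-1.17 ± 0.22) shifted downward. MSC and RAMP1 were also called downward, but each was listed at 0 in a group compared. STEAP2 shifted by -1.75 ± 0.36 with an adjusted p = 0.0165, which was 0.0585 after quantile normalization. Immediate early genes shifted upward in 5 of 14 cases. This was 10 adjusted over the list alone (camera adjusted p = 9.1e-16, adjusted p = 0.00408 with an estimated correlation). Unfolded protein and integrated stress genes did in 6 of 17, led by PSAT1 (2.32 ± 0.30) and HERPUD1 (1.25 ± 0.22). In all 11 passed adjusted over the list alone (camera adjusted p = 7e-11, adjusted p = 0.0739 with an estimated correlation). Interferon-stimulated genes did in 3 of 19, OASL (1.49 ± 0.20), DDX58 (1.16 ± 0.26) and IFIT1 (1.15 ± 0.27), or in 5 without the 5 libraries. The number was 6 adjusted over the list alone (camera adjusted p = 7e-09, adjusted p = 0.372 with an estimated correlation). The count was 144 of 11774 genes, 116 upward and 28 downward, or 169 with the batch term and 151 without the 5 libraries. After quantile normalization 110 shifted upward and 50 downward. The count was 270 with the lines as a block and 92 without wild-type 2D day 4 replicate 3. It was 59 and 266 without AVL9-KD day 0 line 1 and line 4, and 15 on these groups alone.

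Compared directly at day 0, DENND5A-KD cells held more of the fibrillar collagen COL5A1 (2.30 ± 0.28), TMEM45B (1.96 ± 0.27), EGF (1.94 ± 0.22), and CTSK (1.92 ± 0.42) than AVL9-KD cells. The kinase STK26 (1.76 ± 0.18), the Wnt inhibitor APCDD1 (1.64 ± 0.24) and AVL9 (1.66 ± 0.17) were also higher. SPINK6 (-3.48 ± 0.51), STEAP2 (-2.82 ± 0.29), PTGS2 (-2.79 ± 0.40), and GPX2 (-2.12 ± 0.43) were lower. So were the semaphorin receptor NRP2 (-2.08 ± 0.23), CD55 (-1.77 ± 0.35), IGFBP4 (-1.73 ± 0.25) and DENND5A (-1.68 ± 0.14). Interferon-stimulated genes were higher in 3 of 19 cases, IFIT2 (1.07 ± 0.20), IFIT1 (1.03 ± 0.22) and BST2 (0.91 ± 0.21), or in 5 without the 5 libraries. There were 9 adjusted over the list alone (camera adjusted p = 1.69e-08, adjusted p = 0.565 with an estimated correlation). NF-kB and cytokine genes were lower in 4 of 14, led by NFKBIA (-1.18 ± 0.26) and LIF (-1.34 ± 0.30). This was 6 adjusted over the list alone (camera adjusted p = 0.00344, adjusted p = 0.976 with an estimated correlation). With limma 485 of 11774 genes differed, 176 higher and 309 lower at a median of -0.12. The count was 856 with the batch term and 704 without the 5 libraries. Quantile normalization (median -0.01) gave 284 higher and 157 lower. The count was 94 and 220 without DENND5A-KD line 1 and line 2, 299 without AVL9-KD line 1 and 5 on these groups alone.

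In the direct comparison at 2D day 4, all 18 mitosis genes were higher in DENND5A-KD than in AVL9-KD cells, including KIF11 (1.62 ± 0.22), BUB1 (2.23 ± 0.30) and CDC20 (1.45 ± 0.20). In all 18 passed adjusted over the list alone (camera adjusted p = 4.8e-36, adjusted p = 0.0592 with an estimated correlation). DNA replication genes were higher in 11 of 18 cases, led by UHRF1 (1.63 ± 0.15) and MCM5 (1.26 ± 0.18). The number was 15 adjusted over the list alone (camera adjusted p = 3.15e-19, adjusted p = 0.0674 with an estimated correlation). TMEM258 (2.75 ± 0.62), FAM171A1 (2.53 ± 0.22), CTSK (2.47 ± 0.42), TP53I11 (2.26 ± 0.33) and MT1E (2.15 ± 0.52) were higher as well. PTGS2 read 7.24 ± 5.58 (SD, n = 2) FPKM in DENND5A-KD and 85.5 ± 18 (SD, n = 2) in AVL9-KD cells (-3.56 ± 0.40). The collagenase MMP13 (-3.40 ± 0.83), DHRS2 (-3.02 ± 0.57), TGM2 (-2.50 ± 0.28), TAGLN (-2.42 ± 0.41) and TIMP3 (-2.38 ± 0.43) were lower. The small nucleolar RNAs SNORA14 and SNORA8 were called lower, each listed at 0 in both DENND5A-KD libraries. Unfolded protein and integrated stress genes were lower in 11 of 17 cases, led by PSAT1 (-1.34 ± 0.24) and DDIT4 (-1.78 ± 0.32). There were 13 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.702 with an estimated correlation). The p53 targets were lower in 9 of 15, led by PLK2 (-2.31 ± 0.34) and BAX (-0.95 ± 0.17). This was 9 adjusted over the list alone (camera adjusted p = 0.0065, adjusted p = 0.702 with an estimated correlation). YAP and TAZ targets were lower in 10 of 15, led by F3 (-1.69 ± 0.21) and GADD45A (-1.17 ± 0.20). In all 11 passed adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.702 with an estimated correlation). NF-kB and cytokine genes were lower in 8 of 14, led by NFKBIA (-1.40 ± 0.26) and CSF2 (-2.01 ± 0.42). The number was 11 adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.702 with an estimated correlation). Interferon-stimulated genes were lower in 8 of 19 cases, led by OASL (-1.43 ± 0.16) and DDX58 (-1.68 ± 0.21). There were 12 adjusted over the list alone (camera adjusted p = 0.0345, adjusted p = 0.859 with an estimated correlation, adjusted p = 0.063 with the batch term). The count was 2640 of 11774 genes, 386 higher and 2254 lower at a median of -0.24, or 3181 with the batch term and 3023 without the 5 libraries. Quantile normalization (median -0.02) gave 992 higher and 951 lower. It was 349 without DENND5A-KD line 1, 1594 without AVL9-KD line 4, and 0 with limma on these groups alone.

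From 2D day 4 to day 7, DENND5A-KD cells raised the membrane peptidase MME, neprilysin, from 0.823 ± 0.814 (SD, n = 2) to 5.16 ± 0.924 (SD, n = 2) FPKM (1.82 ± 0.30, adjusted p = 0.02). The division genes CDC20 (-1.09 ± 0.20), CASC5 (-1.09 ± 0.19), KIF15 (-1.08 ± 0.17) and UHRF1 (-0.97 ± 0.15) fell. The thromboxane synthase TBXAS1, chosen after its values were seen, rose by 1.33 ± 0.22. Mitosis genes fell as a list, with a median of -1.04 and 17 of 18 lower when adjusted over the list alone but only CDC20 over all genes tested, and none without the 5 libraries (camera adjusted p = 1.59e-37, adjusted p = 0.026 with an estimated correlation). DNA replication genes did too, with a median of -0.51, 13 of 18 lower adjusted over the list alone and only UHRF1 over all genes (camera adjusted p = 8.34e-25, adjusted p = 0.026 with an estimated correlation). Interferon-stimulated genes lay higher relative to other genes (median 0.33, camera adjusted p = 0.000557, adjusted p = 0.791 with an estimated correlation), none passing alone. With limma 6 of 11774 genes changed, 2 higher and 4 lower. The count was 23 with the batch term and 7 without the 5 libraries, and 76 with the lines as a block. Quantile normalization gave 18 higher and 109 lower. With limma it was 0 without line 1 at day 4 and without either line at day 7, and 213 without line 2 at day 4. On all libraries 741 genes had an unadjusted p under 0.05.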

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

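Tests of depth, a batch, the 5 libraries behind the AVL9-KD pattern and scaling behind the mitosis pattern were chosen after the result was seen. So were slopes of falling and rising genes.

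Of the 5 libraries that stand apart, 4 deviated together from their groups, with r of 0.40 to 0.56 across genes. Lower depth is argued against by the AVL9-KD 2D day 4 lines, of relative depth 0.54 and 1.64, whose difference had r of 0.05 with the axis of 3 of these libraries. The day 14 library, which was not used for that axis, lay along it, with r of 0.57 for its difference from 3D day 8 replicate 2. A library or sequencing batch is therefore a candidate explanation. Cultures grown at another time would look the same, and no batch is given in the sources used here.

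Genes called in AVL9-KD at 2D day 4 were mostly higher, 2199 of 2474. That 92.1% of calls were higher without the wild-type libraries that stand apart argues against those as the source. Median changes over 4 quartiles of mean expression ran from 0.187 to 0.238, a range of 0.052, so 1 scaling factor between libraries could give this shift and cannot be told apart from a general rise. Changes such as that of CCL5, at 2.74 ± 0.45, were far larger than this shift.

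Of 18 mitosis genes 17 were higher in DENND5A-KD than in wild-type cells at 2D day 4, although the camera call of the list was lost with an estimated correlation (adjusted p = 0.205). Their median difference was 1.51 without the 5 libraries and 1.46 after quantile normalization, which argues against these libraries and against scaling. A slower course of the change from day 0 may contribute. DENND5A-KD lines had slopes of 0.657 and 0.845 on the wild-type change over 6551 other genes, the second just under the 0.85 set before. Wild type had 0.885 to 1.14 and AVL9-KD lines 0.892 and 1.08. Falling genes had 0.491 and 0.655 (AVL9-KD 0.903 and 1.104), or 0.673 and 0.827 through 0 (0.825 and 1.045). Rising genes had 0.616 and 0.848 (0.765 and 1.036), not setting line 2 apart. Through 0, 338 genes falling as far as mitosis genes had 0.572 and 0.733 (0.907 and 1.122). Mitosis genes had 0.316 and 0.571 (0.996 and 1.342). How much of their difference a slower course explains is open, as are untested differences in handling or between lines.

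The difference between knockdown and wild type changed between day 0 and 2D day 4 for 215 genes in DENND5A-KD and 144 in AVL9-KD. Of the genes named in the results, in log2 units these were BIRC5 1.59, CDC20 1.11, CENPH 1.92, CHRM4 2.64, CLDN2 2.42, CLEC7A 3.15, EGR1 1.78, FOS 2.53, FOSB 2.90, IL1RL1 1.97, MCM5 1.52, MKI67 1.73, TP53I11 2.51 and UHRF1 1.24 upward, and COL4A1 -2.46, CSF2 -2.48, DAB2 -2.07, NTN4 -2.03, RASL11A -2.17, TMEM27 -2.56 and VWA2 -2.66 downward, for DENND5A-KD. For AVL9-KD they were CHAC1 2.77, DDX58 1.16, DTX4 2.41, EGF 2.41, EGR1 3.67, FGF21 2.39, FOS 3.56, FOSB 4.24, HERPUD1 1.25, IFIT1 1.15, OASL 1.49, PRR15L 2.78 and PSAT1 2.32 upward, and RASL11A -1.79, SLIT3 -2.11, STEAP2 -1.75, TMEM27 -2.17, TSPAN5 -1.37 and UBASH3B -1.17 downward. The shifts of FOS, FOSB and EGR1 include the fall of these genes in wild type from day 0, where wild type may be high.

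Among 4 day 0 libraries, a single library lay beyond the critical Dixon ratio in 15 of 220 tests of library measures and named genes, and chance flags about 1 in 20 groups. In FPKM, with the others in brackets, replicate 1 read ATF4 243 (151 to 157), CHAC1 25.3 (7.37 to 9.6), DUSP6 24.8 (18.6 to 19.1), GADD45A 34.3 (20.4 to 22.4), ICAM1 37 (22 to 23.5), SNORA58 78.6 (3.63 to 9.01), TMSB10 180 (2010 to 2250) and TRIB3 19.3 (10.7 to 11.9). Replicate 2 read BBS4 4.43 (3.52 to 3.67), CENPH 26.8 (23.5 to 24) and MSC 0.0336 (0 in the others), replicate 3 LIF 4.5 (7.99 to 8.56) and replicate 4 DTX4 0.0666 (0 in the others), PLK2 35 (43.2 to 44.8) and VIM 1330 (1640 to 1700). Replicate 1 is 1 of the 5 libraries that stand apart.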

How the results depend on the processing

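Counts of changed genes moved by over 1.5 times as follows, and the cause was not tested. For 3D 24 h against day 0 they were 220 with quantile normalization, 310 with median-ratio scaling, 304 with a replicate block and 16 on the groups compared alone. For 2D day 11 against day 4 they were 375 with quantile normalization, 520 with a replicate block, 483 with it as a fixed term, 386 with the batch term and 2 on these groups alone. On the groups compared alone, DENND5A-KD differed from wild type in 400 genes at day 0 and 97 at 2D day 4, AVL9-KD in 342 and 25, and the knockdowns from each other in 5 and, with limma, 0 (4448 at an unadjusted p under 0.05 on all libraries). AVL9 in AVL9-KD at 2D day 4 was then -1.91 (adjusted p = 0.0695). DENND5A-KD at 2D day 4 gave 2069 with quantile normalization. The DENND5A-KD interaction gave 459 with quantile normalization, 455 with median-ratio scaling, 436 with the lines as a block, 445 with a fixed block and 74 on its groups alone, and the AVL9-KD interaction 270, 252 and 15 for the last 3. Between the knockdowns 856 differed at day 0 with the batch term and 1573 at 2D day 4 with median-ratio scaling. DENND5A-KD 2D day 7 against day 4 gave 127 with quantile normalization, 82 with median-ratio scaling, 76 with a block, 14 with a fixed block, 23 with the batch term, 21 with no filter and, with limma at a pseudocount of 0.1, 0 (741 at an unadjusted p under 0.05 in the count of 6). No named gene turned its direction with either scaling, the batch term, no filter or the pseudocount, and no called list its camera direction with either scaling, the batch term, a replicate block or an estimated correlation, although the median of cilium genes at 2D day 11 against day 4 went from -0.02 to 0.01 with the batch term. The majority of calls did so in 8 of 18 contrasts with quantile normalization and in 9 with median-ratio scaling. The results give these counts for the first. With the second, higher and lower genes numbered 128 and 182 for 3D 24 h, 4014 and 3273 for 3D day 5, 4225 and 3516 for day 8, 3593 and 3007 for day 8 against 24 h, 3574 and 3566 for 3D against 2D, 1068 and 1152 for AVL9-KD at day 0, 973 and 851 for DENND5A-KD at 2D day 4, and 412 and 209 and 915 and 658 between the knockdowns.

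Leaving out single libraries gave 17 to 149 genes for 3D 24 h, 0 to 590 for 2D day 11 against day 4, 207 to 641 and 416 to 1217 for DENND5A-KD at day 0 and 2D day 4, 745 to 2572 and 1184 to 2493 for AVL9-KD, and 45 to 419 and 59 to 266 for the interactions. Between the knockdowns the ranges were 94 to 528 and 349 to 2748, for DENND5A-KD day 7 against day 4 0 to 213, and for the other contrasts 4518 to 7300, each within 1.5 times of its count. Majorities turned in 6 contrasts. In wild type the same number gave deviations with r of 0.56, 0.23 and 0.13 between day 0 and 2D day 4 and of 0.04, 0.14 and -0.02 between day 0 and 2D day 11, and the block correlation over all groups was 0.20. All 3 of the first were over 0.1, but replicate 2 minus replicate 3, which leaves out the libraries that stand apart, had r of 0.00 between day 0 and 2D day 4 and -0.15 to 0.15 between other groups. Whether the numbers pair cultures is left open, and no pairing was assumed. Of 468 list tests, 151 passed with camera, 153 after quantile normalization, which lost 11 and gained 13, and 5 with an estimated correlation. In 102 tests, none of them called, a median or direction changed sign with either scaling. Quantile normalization took 4 of the calls given in the results past 0.05, polarity complexes at 3D day 8 (0.11), DENN family and RAB genes at 2D day 11 (0.0576), distal nephron transport in AVL9-KD at day 0 (0.0866) and primary cilium in DENND5A-KD at 2D day 4 (0.0649).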

Other observations

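In genes chosen after their values were seen, the tubule transcription factor PAX8 read 27.3 ± 4.69 (SD, n = 4) FPKM in wild-type cells at day 0 and 66.5 ± 0.753 (SD, n = 3) at 2D day 4. The epithelial adhesion gene EPCAM read 246 ± 23.8 (SD, n = 4) FPKM at day 0 and 285 ± 14.5 (SD, n = 2) at 3D day 8. Transcripts of the mitochondrial genome made up 8.9 to 27.8% of FPKM, lowest in 2D day 11 replicate 2 and highest in 3D day 3 replicate 1.

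Lists of apical trafficking and heat shock genes were called in no contrast, but the first passed with quantile normalization between the knockdowns at day 0 (camera adjusted p = 0.0316). At 3D day 8 apical trafficking genes were 4 higher and 11 lower of 20 (camera adjusted p = 0.42) and heat shock genes 1 higher and 3 lower of 8 (camera adjusted p = 0.682). The other 4 lists were too short to test. Of intercalated cell genes, ATP6V1B1 and RHBG passed the filter and changed by 0.69 ± 0.20 and 0.55 ± 0.21 at 3D day 8. Of fibroblast genes COL5A1 and FBLN1 did, COL5A1 changing by -2.26 ± 0.25 in AVL9-KD cells at day 0, of endothelial genes FLT1, and of leukocyte genes 0.

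Tests of other library groupings were planned, except that of pairs. For 2D day 4 against day 0, 1 of 35 groupings of the 7 libraries, the real one, gave 7055 genes and the highest other 5846. That is the smallest share 35 groupings can give. It argues against chance only where these libraries are exchangeable, which the labels do not settle. Only 8 groupings part all 3 pairs of the same number, too few for a share under 0.05 if the numbers pair cultures. The first holds too for 2D day 11 against day 0 (1 of 35, 6587 genes and 5224). For 3D against 2D (1 of 100, 6696 and 4235) mixed days leave chance open. For 2D day 11 against day 4 the groupings are too few (1 of 10, 245 genes and 1). The other groupings had a median of 0 genes in each case. The highest kept the groups apart but for 1 library of day 0 or 1 of each group.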
